A study of Homo sapiens with 3 samples.

How the data were processed

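The series holds 3 Agilent single-colour (Cy3) arrays, 1 each for xenograft tumours of HCT116, HCT/OHP1 and HCT/OHP5 cells grown under the skin of nude mice, with RNA isolated with TRIzol per the labels' protocols. All 3 arrays were on the same slide and were scanned together per the file headers, so that slide and scan do not differ between the sources. The labels hold 1 array per source and state no pooling and no tumour of a second mouse.

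Spot intensities were read from the deposited files as the processed signal. This is the background-subtracted, detrended intensity of each spot on a linear scale, made with Agilent Feature Extraction 11.5.1.1 per the file headers, with no scaling between arrays. The submitters' processing notes give version 10.7.3.1 of the same program. The authors' value table holds the same intensity of each spot times 1 constant per array (5.3034 for HCT116, 5.5726 for HCT/OHP1 and 5.0854 for HCT/OHP5), also linear. How these constants were chosen is stated nowhere in the files and stays unknown. The medians of that table were 96.1, 119.9 and 98.2, so that it does not bring the arrays to a common median.

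Each array had 58717 spots that were not controls, for 50599 probes. Spots called outliers by the extraction program were left out (328 on the HCT116 array, 256 on HCT/OHP1 and 330 on HCT/OHP5), which left 50593 probes, and 0 spots were saturated. The processed signals were averaged per probe on the log2 scale and the 75th percentile of each array was subtracted (signals of 180.6, 196.6 and 188.6). Probes were joined to gene symbols through their transcript accessions and the name table given with the series, which follows human assembly GRCh38, while the array annotation names build hg19. No coordinates are therefore given. A symbol was found for 30271 probes of 21741 genes, and 20322 probes, mostly of unnamed transcripts, stayed without one. For the 6287 genes with more than 1 probe, the probe with the highest mean over the 3 arrays gave the value. The lowest signals called well above background by the extraction program were 7.32, 5.87 and 6.32.

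The precision of the arrays was estimated from 902 probes printed at more than 1 spot and from genes with several probes. For probes of 3928 and 3878 genes the log2 ratios to HCT116 had the spreads given in the text, and the SD was 0.42 between the clones (3969 genes). The mean log2 ratios of 8 spike-in probes (E1A) were 0.02 for HCT/OHP1 over HCT116, −0.01 for HCT/OHP5 over HCT116 and −0.03 between the clones. Saturation did not limit the upper end, and ratios of dim genes are bounds.

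The comparisons made were HCT/OHP1 with HCT116, HCT/OHP5 with HCT116, HCT/OHP5 with HCT/OHP1, and the overlap of the first 2. A gene was considered when its main probe was well above background on at least 1 of the 2 arrays, and counted at 2-fold or more. When the gene was dim on 1 array, the ratio was taken as a lower bound, with the dim value set to the higher of that array's lowest signal above background and the probe's own signal. The rule of size, the probe choice, 25 gene lists, the rule for genes to name and the alternatives were fixed before the data were examined, except where the text says otherwise. The named genes were the 10 highest and 10 lowest ratios of each comparison on genes above background on both arrays, the 5 largest bounds each way against HCT116, the 10 highest and lowest in both clones by the smaller ratio, the 5 genes at least 2-fold from HCT116 in opposite directions with the largest smaller ratio, up to 4 members per list and all measured transporters. Genes whose other probes went the other way were left out of the first set (1 gene, LINC01564). Further list members were named after their values had been seen, mostly where a count was 5 or fewer. XIST and Y-linked genes were not named, and values of some list members are not reported here.

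The lists were platinum and drug transporters, glutathione and NRF2-regulated detoxification, metallothioneins, DNA repair, p53 targets, the BCL2 family and inhibitors of apoptosis, proliferation, hypoxia response, glycolysis, oxidative phosphorylation, mesenchymal, epithelial, intestinal differentiation, stem-like and Wnt targets, interferon response, NF-kB cytokines, EGFR ligands and ERK-induced genes, unfolded protein and amino acid stress, cholesterol and fatty acid synthesis, fluoropyrimidine and nucleotide metabolism, and housekeeping. The remaining 4 lists held markers of other cell types, which were fibroblasts, endothelium, leukocytes, and skin, fat, muscle and blood. For each list the median log2 ratio was placed among the medians of 10000 random lists with the same number of genes in each of 20 bins of mean signal. The percentile describes these arrays only, since genes are not independent replicates of a tumour. Lists below percentile 2.5 or above 97.5 were taken as outside the random lists.

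Counts expected with no difference were simulated 100 times with repeat-spot noise and with the noise between probes of 1 gene, keeping the shared HCT116 array. Repeat-spot noise gave 42.6 higher and 38.1 lower genes for HCT/OHP1, 31.8 and 34.6 for HCT/OHP5. Probe noise gave 109 and 106 for HCT/OHP1, and 107 and 106 for HCT/OHP5. The computations were tested on simulated arrays of 21741 genes with repeat-spot noise only and 200 genes changed by known folds. The rule called 2.5% of genes changed 1.5-fold, 50% at 2-fold, 100% at 3-fold, 95% at 4-fold, 97.5% at 8-fold, 0 in the wrong direction, and 0.37% of unchanged genes. The 0.37% leaves out differences between probes and between tumours, so it is no error rate for calls between tumours. Of 40 unchanged lists 1 fell outside the random lists.

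The alternatives were the mean of all probes of a gene, outlier spots kept, scaling on the median of probes above background on all arrays, quantile normalization, normexp background correction (offset 50), no filter on dim probes, only genes above background on every array compared, the authors' value table and a 3-fold threshold. Normexp had been planned on mean spot signals, which the files do not hold, and used median spot and background signals instead. Loess correction of ratios on signal and scaling on the E1A probes were added after the data were seen. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, with R 4.3.3 and limma 3.58.1 for normexp.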

Results

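Gene expression was measured in xenograft tumours from 3 sources. These were HCT116, a human colorectal cancer cell line, and HCT/OHP1 and HCT/OHP5, which are clones of HCT116 resistant to oxaliplatin, a platinum drug that forms adducts with DNA. The cells had been inoculated under the skin of nude mice, and the tumours received no drug. One RNA sample per source was hybridised to 1 Agilent single-colour array, so each source had n = 1 and no spread between tumours could be measured. No p-value is given for any difference. A gene was counted as higher or lower when its normalised signal differed at least 2-fold between the 2 arrays compared. Its main probe was well above background for 15345 of 21741 genes in HCT116 (70.6%), for 16059 in HCT/OHP1 (73.9%) and for 15506 in HCT/OHP5 (71.3%), and 14768 genes were above background on all 3 arrays. Repeat spots of 1 probe differed with an SD of 0.13 on the log2 scale where they were above background and 0.47 where they were not. Different probes of 1 gene gave log2 ratios with an SD of 0.45 for HCT/OHP1 over HCT116 and 0.34 for HCT/OHP5 over HCT116. These are technical errors, and the number of arrays limits the precision of every value that follows.

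The first comparison was between HCT/OHP1 and HCT116 tumours. HCT/OHP1 had higher signals of interferon-induced genes, of fibroblast markers and of several genes of the muscle sarcomere, and lower signals of genes of the hypoxia response, glycolysis and lipid synthesis. Of 16368 genes above background on at least 1 of the 2 arrays, 1587 were at least 2-fold higher in HCT/OHP1 and 1302 were at least 2-fold lower. The ratios of 1282 and 1119 of them were measured on both arrays, and those of 305 and 183 were lower bounds, because the gene was not well above background on 1 array.

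Among genes measured on both arrays, ATP2A1, the calcium pump of fast muscle, was 392-fold higher in HCT/OHP1 (log2 ratio 8.61, and 6.86 by another probe). TNNI2 and TNNT3, troponin subunits of fast muscle, were 187-fold and 50-fold higher, and MYOZ1 and MYL11, a Z-disc protein and a myosin light chain, were 111-fold and 55.9-fold higher. The other genes among the 10 highest were the interferon-induced chaperone RTP4 (89.2-fold), MSMP (64.7-fold), TCEAL5 (52.5-fold), SUSD2 (50.5-fold) and the RAS-like GTPase DIRAS3 (48.1-fold). Another 5 genes were not well above background in HCT116. MYL1 was at least 423-fold higher in HCT/OHP1, KLHL41 at least 117-fold, MYOT at least 91.1-fold, the myosin heavy chain gene MYH4 at least 74.5-fold and the muscle glycogen phosphorylase gene PYGM at least 65.7-fold.

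Among genes measured on both arrays, those with the lowest ratios in HCT/OHP1 were LY6D (254-fold lower, log2 ratio −7.99) and the annexin gene ANXA10 (208-fold lower). The dipeptidyl peptidase gene DPP4 was 132-fold lower, ACKR5 122-fold, GPR179 93.0-fold, the keratin gene KRT79 85.7-fold, CD86 80.7-fold, RPA4 72.6-fold and LRRC2 69.0-fold. CA9, a carbonic anhydrase induced by low oxygen, was 68.2-fold lower. Lower bounds were 103-fold for LINC02148, 74.4-fold for BICC1, 50.6-fold for the dipeptidase gene DPEP1, 47.7-fold for MSRB3-AS1 and 35.7-fold for LINC01667. Of these genes, DPP4, ACKR5, GPR179, KRT79, CD86, RPA4, LRRC2, CA9, LINC02148, BICC1 and LINC01667 belonged to 48 probes with nearly equal ratios in HCT/OHP5 (median log2 ratio −2.60). Only 4 of the 19 named genes of that group had another probe above background in HCT116, and for 3 of these 4 the other probe was not 2-fold lower in HCT/OHP1. The values of these 11 genes are therefore those of single probes.

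Of 22 measured genes of the hypoxia response list, 18 were at least 2-fold lower in HCT/OHP1 and 1, the collagen crosslinking gene LOX, was higher. The median log2 ratio of the list was −1.88, below all 10000 random lists of the same size and expression. Besides CA9, the stress gene NDRG1 had a log2 ratio of −3.42, and the adrenomedullin gene ADM was 7.96-fold lower, ANGPTL4 7.6-fold and the pyruvate dehydrogenase kinase gene PDK1 7.08-fold. Of 18 glycolysis genes, 9 were lower and 0 higher, with a median of −1.07 that was also below all random lists. Hexokinase HK2 was 10.8-fold lower, the glucose transporter gene SLC2A1 4.75-fold, GPI 4.27-fold, GAPDH 3.95-fold and LDHA 2.84-fold. Of 25 genes of cholesterol and fatty acid synthesis, 13 were lower and 0 higher, with a median of −1.02, again below all random lists. Fatty acid synthase FASN was 3.48-fold lower, INSIG1 3.27-fold and ACACA 3.07-fold.

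Among 31 measured genes of the interferon response, 23 were at least 2-fold higher in HCT/OHP1 and 0 were lower, and the median log2 ratio of 1.55 was above all random lists. XAF1 was 27.7-fold higher, IFI44L 19.4-fold, the oligoadenylate synthetase gene OAS2 15.8-fold and the immunoproteasome subunit gene PSMB9 10.8-fold. Of 15 measured NF-kB cytokine genes 6 were higher and 0 lower (median 0.69, percentile 99.9 among random lists, but 94.1 over genes above background on both arrays and 94.2 without a filter on dim probes). The chemokine gene CXCL1 was 4.28-fold higher and CXCL2 3.41-fold. The list of mesenchymal genes had 10 of 19 members higher and 2 lower (median 1.0, above all random lists). Its transcription factors ZEB2 and SNAI2 were 4.5-fold and 4.47-fold higher, the integrin gene ITGA5 was 3.62-fold lower, and vimentin (VIM) had a log2 ratio of −0.14. Fibroblast markers, which mark another cell type and overlap with mesenchymal programmes, were higher for 9 of 10 measured genes (median 2.32, above all random lists). This list shares MMP2 with the mesenchymal list. Host cells in these tumours are of mouse and the probes are human, with unknown match to mouse sequence. Whether tumour or host cells gave the fibroblast and endothelial signals, in either clone, is therefore not known. ACTA2 was 9.13-fold higher, FAP 8.85-fold and DCN 6.43-fold. Endothelial markers were higher for 3 of 8 genes (median 1.10, percentile 98.5, but 95.6 with normexp background correction), among them ENG (4.37-fold) and TIE1 (2.83-fold).

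Smaller shifts of whole lists were also present in HCT/OHP1. The 28 measured p53 targets had a median of 0.23 (percentile 99.3), with 2 genes higher and 1 lower. GDF15, a secreted cytokine, was 4.3-fold higher, the death receptor gene FAS 2.81-fold higher, and SPATA18 at least 2.5-fold lower. Genes of the unfolded protein and amino acid stress list had a median of 0.26 (percentile 99.9), with 1 of 22 higher, CHAC1 (2.97-fold), and 1 lower, SHMT2 (3.2-fold). Proliferation genes had a median of −0.41, just outside the random lists (percentile 2.39), with 1 of 29 lower, BUB1 (2.44-fold). They lay within the random lists with loess correction (percentile 7.26), quantile normalization (4.58), normexp (3.58) and no filter on dim probes (2.91). The replication genes MCM7 and MCM6 and the marker gene MKI67 had log2 ratios of −0.99, −0.79 and −0.69. Of 16 measured genes of intestinal differentiation, 5 were lower and 0 higher (median −0.44, percentile 1.19, but 17.8 over genes above background on both arrays and 5.06 without a filter on dim probes). The 5 were DPP4, the mucosal peptide gene TFF2, PHGR1 (at least 32.9-fold), KRT20 (at least 6.35-fold) and CEACAM6 (at least 6.08-fold).

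The 13 other lists had medians within the middle of the random lists in HCT/OHP1 in the main setting. Metallothioneins (percentile 95.5) lay above them with quantile normalization (99.2), loess correction (98.2) and no filter on dim probes (98.2), and glutathione genes (71.4) with quantile normalization (98.3, median 0.29). Over genes above background on both arrays, skin, fat, muscle and blood markers (98.8) and epithelial genes (97.6) lay above them, the latter also without a filter on dim probes (97.54), and housekeeping genes lay below them with the mean of all probes (2.35). Of 13 measured platinum and drug transporters, 1 was higher and 1 lower. The copper chaperone gene ATOX1 was 2.29-fold higher, and the efflux pump gene ABCC2 was 13.1-fold lower. The other 11 did not reach 2-fold by their main probes. Their log2 ratios included −0.84 for the copper importer gene SLC31A1, 0.73 for SLC31A2, −0.46 for ATP7A, −0.17 for ATP7B, −0.74 for ABCC1, 0.59 for ABCC3, −0.56 for ABCC4 and 0.43 for ABCC5. ABCB1 and ABCG2 were not well above background in HCT116 and were at least 1.46-fold and at least 1.4-fold higher. A second SLC31A1 probe gave 0.21, and the other ABCC5 probes gave 0.97 and 1.30, the latter past 2-fold. Glutathione and NRF2-regulated genes were higher for 6 of 28 and lower for 1, the glutathione reductase gene GSR (2.08-fold). The cystine transporter gene SLC7A11 was 7.48-fold higher, AKR1C1 5.05-fold, AKR1B10 at least 4.36-fold and AKR1C3 2.71-fold. For AKR1C1 the log2 ratio was 2.34 by the main probe and 1.71 by another. Of 36 DNA repair genes 2 were higher, the nuclease gene ERCC4 (2.28-fold) and REV3L (2.05-fold), and 0 were lower. A second ERCC4 probe gave a log2 ratio of 0.41, below 2-fold. The mismatch repair genes MSH6 and MSH3 had log2 ratios of −0.97 and 0.90. Of 8 measured metallothioneins MT1F was higher (3.09-fold) and 0 were lower, with log2 ratios of −0.23 for MT1E and 0.52 for MT3. Among 20 genes of the BCL2 family and inhibitors of apoptosis 4 were higher, BCL2 (6.62-fold), BIRC3 (2.26-fold), BCL2L11 (2.17-fold, with log2 ratios of 0.52 and 1.81 by its other probes) and BCL2L1, and 0 lower. The EGFR ligands and ERK-induced genes had 7 of 20 members lower and 1 higher, with the ligand genes EREG and AREG 21.1-fold and 15.4-fold lower and the early response gene FOS 4.52-fold lower. Stem-like and Wnt targets had 2 of 16 higher and 2 lower, with SP5 10.2-fold and TCF7 2.63-fold higher and MYC 6.64-fold and PROM1 2.77-fold lower. The nucleotidase gene NT5E was the 1 higher gene of 15 in fluoropyrimidine and nucleotide metabolism (7.04-fold), and the cytidine deaminase gene CDA the 1 lower (2.1-fold). Of 22 oxidative phosphorylation genes 0 passed 2-fold in either direction (median −0.45, percentile 10.6), with log2 ratios of −0.80 for NDUFV1, −0.74 for CYC1, −0.64 for COX5A and −0.64 for UQCRC2. Of 14 housekeeping genes 3 were lower, GAPDH, TFRC (2.76-fold) and HPRT1 (2.66-fold), with a median of −0.53 (percentile 6.2). Epithelial genes had 1 of 18 higher, the tight junction gene OCLN (2.12-fold), and 2 lower, ELF3 (7.63-fold) and DSP (2.68-fold). Leukocyte markers had 1 of 10 higher, CD3E (2.12-fold), and 3 lower, CD68 (6.89-fold), NKG7 (at least 2-fold) and, by its main probe, PTPRC. The log2 ratio of PTPRC turned from −1.43 to 0.27 with normexp background correction, and another PTPRC probe gave 1.09, so that no direction is given for this gene. Skin, fat, muscle and blood markers had 2 of 10 higher, TNNT3 and HBA2 (5.38-fold, with log2 ratios of 2.37 and 0.38 by its other probes), and 3 lower, KRT14 (13.3-fold), CKM (at least 3.45-fold) and KRT5 (2.81-fold). The medians of the transporter, glutathione, DNA repair, EGFR, fluoropyrimidine and leukocyte lists lay just below 0, within the shift of all genes alike that the authors' value table brings, so no direction is given for them.

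The settings for background and scaling moved the counts of this comparison. With normexp background correction, which shrinks ratios of dim probes, 782 genes were higher and 647 lower, and without a filter on dim probes 2499 were higher. With the authors' value table, 2142 were higher and 887 lower, so that 70.7% of the calls were higher against 54.9% in the main setting, and the median log2 ratio of genes above background on all arrays moved from −0.10 to 0.10.

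**Figure D1:**
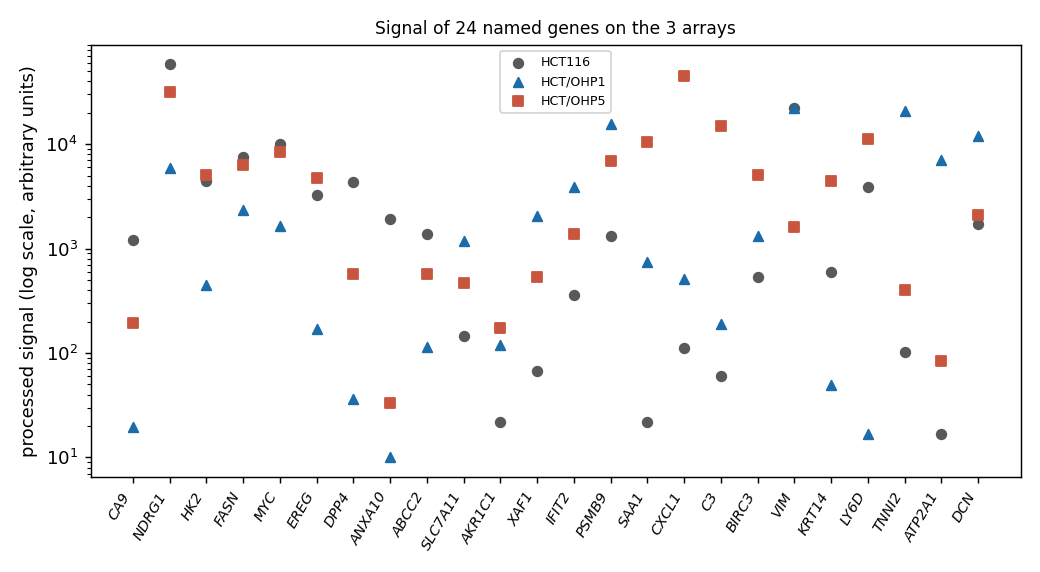
Processed signal, on a log axis in arbitrary units, of 24 named genes on the HCT116, HCT/OHP1 and HCT/OHP5 arrays, with 1 point per array and no replicates. CXCL1 reads 44818.5 in HCT/OHP5 against 111.1 in HCT116, and LY6D reads 16.8 in HCT/OHP1 against 3930.7 in HCT116.

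The second comparison was between HCT/OHP5 and HCT116 tumours. Serum amyloid genes and the list of NF-kB cytokine genes were far higher in HCT/OHP5, interferon-induced genes were higher as well, and vimentin was lower. Of 15940 genes, 994 were at least 2-fold higher in HCT/OHP5 (215 of them as lower bounds) and 862 at least 2-fold lower (184 as lower bounds). SAA1 and SAA2, which encode acute phase serum amyloid A, were 455-fold and 451-fold higher. The HCT116 signal of SAA2 was 11.6, near the lowest signal above background (7.32), so the size of its ratio is uncertain. CXCL1 was 386-fold higher, the elastase inhibitor gene PI3 283-fold, complement component C3 235-fold, CXCL2 163-fold and the xanthine dehydrogenase gene XDH 80.2-fold. CCL28, PLAC8 and the epithelial transcription factor gene EHF were 66.5-fold, 63.6-fold and 56.0-fold higher. Against an HCT116 signal that was not well above background, CXCL3 was at least 180-fold higher, CXCL8 at least 104-fold, PADI1 at least 101-fold, IL20RA at least 76.1-fold and the amino acid transporter gene SLC6A14 at least 57.7-fold. SAA1 and SAA2, like CXCL1, CXCL2 and CXCL3, are close paralogues whose probes may not be fully specific.

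The lowest ratios in HCT/OHP5 among genes measured on both arrays were those of ANXA10 (60.2-fold lower, log2 ratio −5.91), the amino acid transporter gene SLC38A5 (55.5-fold) and the cytokine gene TNFSF4 (49.8-fold). APOC1 was 21.3-fold lower, SCG2 19.1-fold, the collagen receptor gene MRC2 18.9-fold, COXFA4L2 18.5-fold, BTBD16 17.8-fold, RINL 15.8-fold and RPRML 14.4-fold. Lower bounds were 45.1-fold for DPEP1, 37.3-fold for UTS2B, 29.5-fold for KLHDC9, 23.0-fold for FOXS1 and 19.1-fold for ZNF426.

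In HCT/OHP5, 14 of 19 measured NF-kB cytokine genes were at least 2-fold higher and 0 lower (median log2 ratio 2.69, above all 10000 random lists). The NF-kB inhibitors TNFAIP3 and NFKBIA were 12.8-fold and 4.3-fold higher, TNF was at least 23.5-fold and CCL20 at least 38.3-fold higher. Of 31 interferon response genes 17 were higher and 0 lower (median 1.07, above all random lists), with XAF1 7.53-fold, IFI44L 5.35-fold, PSMB9 5.07-fold and IFIT2 3.68-fold higher. Epithelial genes had a median of 0.45, above all random lists, with 2 of 19 higher, the tight junction gene CLDN1 (at least 45.2-fold) and GRHL2 (2.53-fold), and 0 lower. Fibroblast markers were higher for 5 of 10 genes (median 1.01, above all random lists), including ACTA2 (2.51-fold) and PDGFRA (2.62-fold). Of 7 measured endothelial markers 2 were higher, ROBO4 (at least 21.4-fold) and FLT1 (at least 3.02-fold), with a median of 0.70 (percentile 98.8, but 68.6 over the 5 genes above background on both arrays). Skin, fat, muscle and blood markers were higher for 3 of 9 genes (median 0.79, percentile 99.9), which were the creatine kinase gene CKM (9.62-fold), KRT14 (7.11-fold) and the alpha globin gene HBA2 (5.39-fold, with log2 ratios of 2.28 and 0.19 by its other probes).

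Other lists were shifted little in HCT/OHP5, and 3 of them stood outside the random lists in only part of the settings. Unfolded protein and amino acid stress genes had a median of 0.24 (percentile 99.7), with CEBPB (3.5-fold) the 1 of 22 higher and the pseudokinase gene TRIB3 at a log2 ratio of 0.96. Cholesterol and fatty acid synthesis had a median of 0.16 (percentile 97.8, but 93.5 with the mean of all probes of a gene) with 0 of 25 genes past 2-fold. The fluoropyrimidine list had a median of 0.22 (percentile 98.2) with 2 of 15 higher, the dihydropyrimidine dehydrogenase gene DPYD (3.34-fold) and NT5E (3.26-fold, with a log2 ratio of 0.77 by another probe). Its percentile was 93.9 with normexp, 94.1 without a filter on dim probes, 97.1 with loess correction and 97.3 with the mean of all probes. Below 0 lay the p53 targets (median −0.34, percentile 0.06), with 2 of 28 lower, PMAIP1 (2.51-fold) and ZMAT3 (2.07-fold). The hypoxia list had a median of −0.33 (percentile 0.11) with 2 of 22 lower, CA9 (6.58-fold, of the same 48 probes) and CA12 (at least 9.96-fold). The EGFR and ERK list had a median of −0.21 (percentile 2.0, but 2.53 with loess correction) with 2 of 20 higher, HBEGF (4.99-fold) and IER3, and 2 lower, SPRY4 and FOSL1.

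The remaining 13 lists had medians within the middle of the random lists in HCT/OHP5 in the main setting. The apoptosis list (percentile 96.2) lay above them with normexp (98.5), loess correction (97.6) and quantile normalization (97.54). Of 12 measured transporters only ABCC2 passed 2-fold, at 2.51-fold lower, and ATOX1 had a log2 ratio of 0.65. SLC31A1 stood at 0.33, SLC31A2 at 0.44, ATP7A at −0.31, ATP7B at −0.08, ABCC1 at −0.39, ABCC3 at −0.24, ABCC4 at −0.58 and ABCC5 at −0.25, and ABCG2 was at least 1.16-fold higher. Glutathione and NRF2-regulated genes were higher for 3 of 28, AKR1C1 (7.77-fold), SLC7A11 (3.15-fold) and AKR1C3 (2.87-fold), and lower for GSTA4 (2.37-fold). For AKR1C1 the log2 ratio was 2.96 by the main probe and 1.86 by another, so its size is uncertain. Mesenchymal genes had 1 of 19 higher, CCN2 (2.89-fold), and 4 lower (median −0.20), VIM (14.4-fold), TGFB2, SPARC and AXL. Stem-like and Wnt targets had 2 of 16 higher, SP5 (5.81-fold) and DKK1 (2.73-fold), and 1 lower, CD44 (3.54-fold). The apoptosis list had 2 of 20 higher, BIRC3 (9.25-fold) and BCL2 (2.26-fold), and 1 lower, PMAIP1. ERCC4 (2.41-fold higher, with a log2 ratio of 0.57 by another probe) was the 1 DNA repair gene of 36 past 2-fold, MT1M (2.11-fold lower) the 1 metallothionein of 8, and SLC2A3 (7.39-fold lower) the 1 glycolysis gene of 18. Intestinal differentiation had 2 of 18 higher, the aminopeptidase gene ANPEP (8.39-fold) and SPINK4 (at least 2.09-fold), and 3 lower, PHGR1 (9.46-fold), DPP4 and KRT20 (2.7-fold). Of 29 proliferation genes, 22 oxidative phosphorylation genes and 14 housekeeping genes 0 passed 2-fold, and leukocyte markers had 1 of 13 higher, S100A9 (at least 6.12-fold). With normexp background correction the counts of this comparison were 463 higher and 315 lower, and without a filter on dim probes they were 1648 and 1474.

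**Figure D2:**
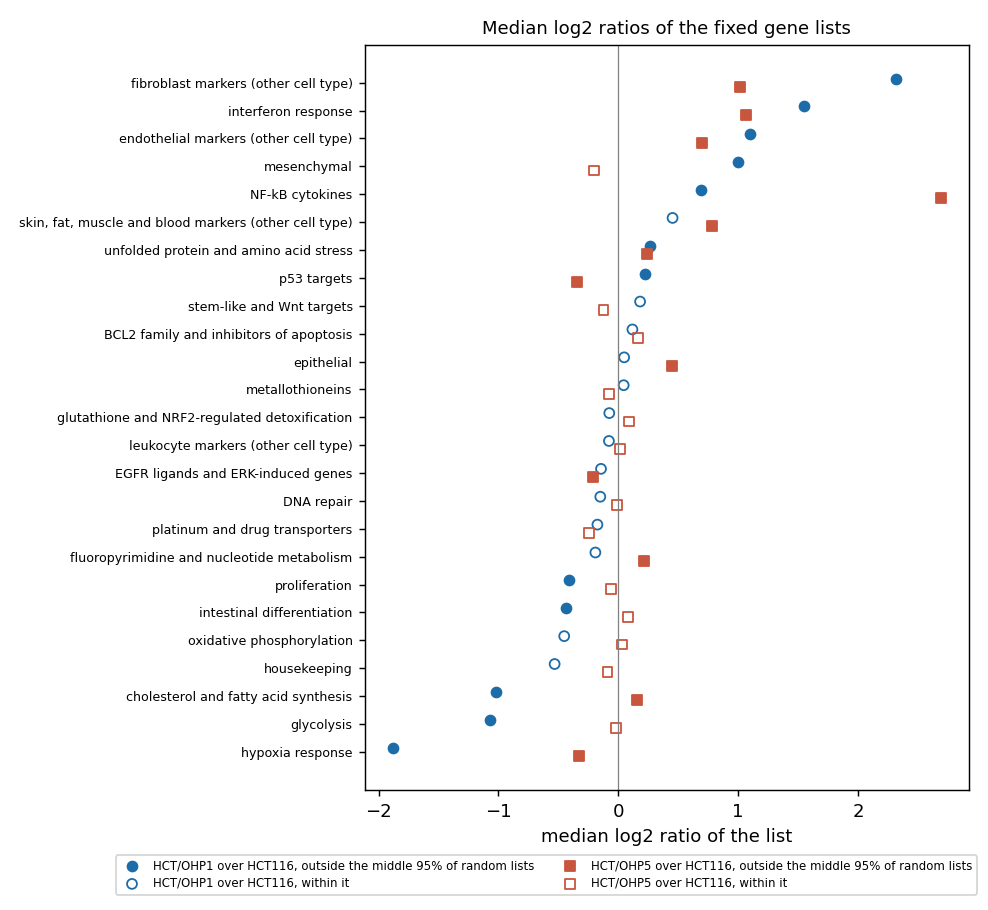
Median log2 ratio of each fixed gene list, for HCT/OHP1 over HCT116 (circles) and HCT/OHP5 over HCT116 (squares), with filled symbols for medians outside the middle 95% of random lists matched on expression. The hypoxia list lies at −1.88 in HCT/OHP1 and −0.33 in HCT/OHP5, and the NF-kB list at 0.69 and 2.69.

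The next comparison asked how far the clones differed from HCT116 in the same genes. Both clones had at least 2-fold higher signals for 470 genes and lower signals for 345. Lists that were independent would share 83.7 and 71.4 of the 15726 genes considered in both comparisons, and 106 genes lay on opposite sides of HCT116 where independent lists would give 154.6. Both ratios use the same HCT116 array, so its errors enter both. Arrays simulated with no difference and the noise between probes of 1 gene gave 12.1 and 11.5 such genes. Across 16582 genes the log2 ratios of the clones had a Pearson correlation of 0.45 and a Spearman correlation of 0.42, which describes genes and not replicates. The shared array alone gives 0.50 with no difference at all. The covariance of 0.449 exceeded the simulated 0.083 by 0.366. The single HCT116 array could not be divided, and part of the excess overlap may come from it.

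Among genes above background on all 3 arrays, the highest in both clones by the smaller ratio were SAA2 and SAA1, with 47.5-fold and 30.9-fold in HCT/OHP1 beside the values given for HCT/OHP5. The haptoglobin-related gene HPR was 46.5-fold higher in HCT/OHP1 and 53.9-fold higher in HCT/OHP5, and the transcription factor gene FOXQ1 30.8-fold and 44.0-fold. RTP4 (19.6-fold), SUSD2 (18.0-fold), CSGALNACT1 (16.9-fold), C6orf15 (32.8-fold), the kallikrein gene KLK5 (53-fold) and CCL28 were also among the 10 highest, with these values in HCT/OHP5. In HCT/OHP1 the last 4 were 36.5-fold, 22.4-fold, 19.4-fold and 14.4-fold higher. C6orf15 (8.2), RTP4 (9.8), KLK5 (10.9) and SAA2 (11.6) read near the lowest signal above background (7.32) in HCT116, so their ratios are uncertain in size. Lowest in both were ANXA10 and APOC1, the latter 36.0-fold lower in HCT/OHP1. There APOC1 read 8.4, near the lowest signal above background (5.87), so the size of this ratio is uncertain too. The stem cell factor gene KITLG was 12.5-fold lower in HCT/OHP1 and 13.1-fold lower in HCT/OHP5. IGF2BP3, an RNA-binding protein gene, was 15.1-fold and 9.89-fold lower, IGFL2 14.2-fold and 9.76-fold, BTBD16 12.7-fold and 17.8-fold, NKAIN1 8.6-fold and 8.35-fold, and the imprinted RNA H19 9.37-fold and 7.51-fold. DPP4 and KRT79, 8.03-fold and 7.5-fold lower in HCT/OHP5, completed the 10, and both belonged to the 48 probes with nearly equal ratios in HCT/OHP5. With normexp background correction 179 genes were higher and 140 lower in both clones, and without a filter on dim probes 810 and 628. The genes on opposite sides of HCT116 numbered 25 and 178 in these 2 settings, against 106 in the main one.

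**Figure D3:**
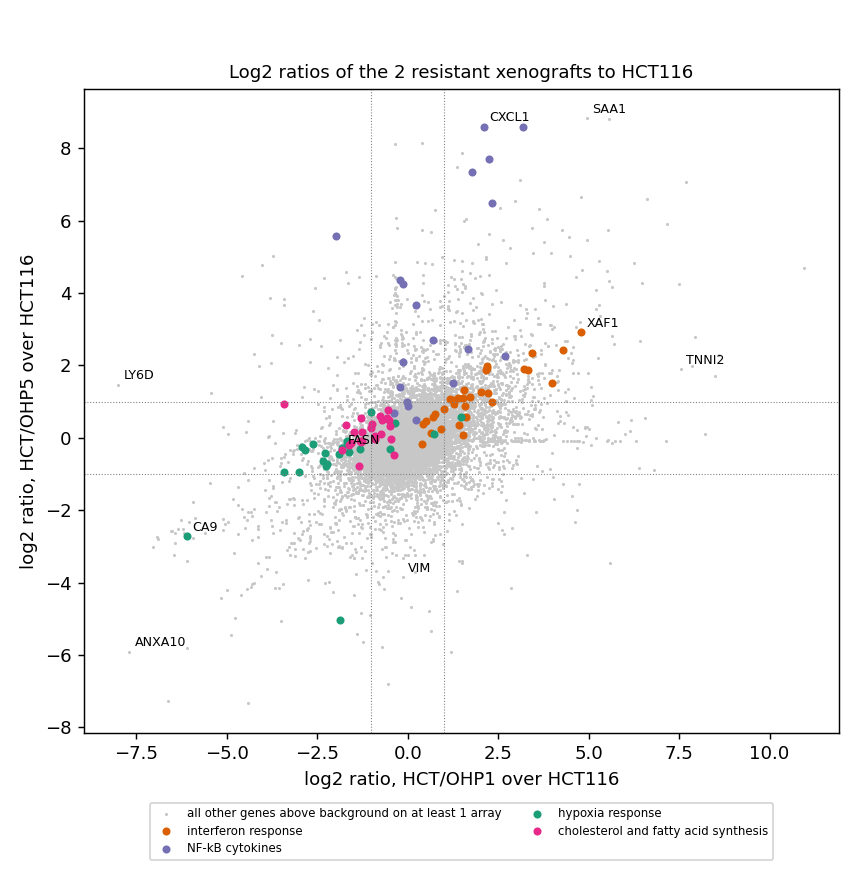
Log2 ratio to HCT116 in HCT/OHP5 (vertical axis) against that in HCT/OHP1 (horizontal axis), 1 point per gene above background on at least 1 array, Y-linked genes and XIST left out, with dotted lines at 2-fold. Interferon genes (orange) lie at positive values on both axes for XAF1 (4.79 and 2.91), whereas FASN of the cholesterol list (pink) lies at −1.80 and −0.33.

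The direct comparison of the clones set HCT/OHP5 against HCT/OHP1. The keratin genes KRT14 and KRT17 and the list of NF-kB cytokine genes were higher in HCT/OHP5, and mesenchymal genes and several genes of the muscle sarcomere were higher in HCT/OHP1. Of 16416 genes, 1292 were at least 2-fold higher in HCT/OHP5 and 1608 lower. Among genes above background on both arrays, the highest ratios were those of LY6D (700-fold), the calcium-binding protein gene S100P (442-fold), PI3 (213-fold), the fucosyltransferase gene FUT3 (202-fold), TRIM29 (106-fold), the lipocalin gene LCN2 (105-fold), KRT14 (94.9-fold), CXCL1 (90.4-fold), C3 (82.4-fold) and KRT17 (69.4-fold). The lowest among them were those of MYOT (110-fold lower), ATP2A1 (80.7-fold), MYL1 (76.8-fold), MSMP (60.1-fold), LHFPL6 (58.9-fold), TNNT3 (55.0-fold), PYGM (51.4-fold), TNNI2 (50.5-fold), MRC2 (48.3-fold) and MYL11 (41.0-fold). In HCT/OHP5 MYOT (6.3), LHFPL6 (7.9) and PYGM (9.8) read at or near the lowest signal above background (6.32). FUT3 read 10.5 in HCT/OHP1, where that signal was 5.87. The ratios of these 4 genes are therefore uncertain in size. Bounds as far out, for genes dim on 1 of these arrays, included DSG3 (at least 312-fold higher), MYOZ1 (at least 205-fold lower) and DIRAS3 (at least 151-fold lower). S100P, FUT3, KRT14, the desmoglein gene DSG3 and the keratin pseudogene KRT42P lay farthest from HCT116 in opposite directions by the smaller of their 2 ratios. In HCT/OHP1 they were 16.3-fold, 13.9-fold, 13.3-fold, at least 9.62-fold and 6.53-fold lower, and in HCT/OHP5 they were 27.1-fold, 14.5-fold, 7.11-fold, 32.4-fold and 6.65-fold higher. KRT14, KRT17 and KRT42P are paralogues, and a second KRT42P probe gave log2 ratios of −0.52 and 0.58.

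Between the clones, 18 of 25 genes of cholesterol and fatty acid synthesis were higher in HCT/OHP5 (median 1.24), as were 16 of 22 hypoxia genes, with 1 lower (1.51), 12 of 18 glycolysis genes, with 1 lower (1.10), and 13 of 19 NF-kB cytokine genes (2.24), and each of these medians was above all random lists. Epithelial genes (4 of 19 higher, median 0.55, percentile 99.4), intestinal differentiation genes (7 of 19 higher, 0.47, percentile 99.6) and leukocyte markers (5 of 13 higher, 0.69, percentile 99.7) also lay above the random lists in the main setting. Over genes above background on both arrays their percentiles were 96.2, 89.7 and 27.6, and the median of the leukocyte markers was −0.15. With the mean of all probes of a gene, epithelial genes were at 81.8 and leukocyte markers at 93.2, and with normexp and without a filter on dim probes leukocyte markers were at 54.3 and 88.1. Lower in HCT/OHP5 were 13 of 19 mesenchymal genes, with 1 higher (median −1.27), 6 of 10 fibroblast markers (−1.34), 10 of 31 interferon genes (−0.56) and 6 of 28 p53 targets (−0.69), each below all random lists. Stem-like and Wnt targets (−0.43, percentile 0.32) and metallothioneins (−0.35, percentile 0.1) lay below them. Of the 16 Wnt genes 2 were lower and 2 higher, MYC (5.36-fold) and PROM1 (3.46-fold), and of the 8 metallothioneins 1 was lower. The number of lists outside the middle 95% of random lists was 12 of 25 in HCT/OHP1, 12 in HCT/OHP5 and 13 between the clones. For lists of unrelated genes 1.25 would be expected by chance in each comparison. Genes of 1 list can change together, and some lists share genes, such as SLC2A1 in hypoxia and glycolysis. The number 1.25 is therefore no test of these counts. In the authors' values 901 genes were higher and 2112 lower in HCT/OHP5 than in HCT/OHP1, so that 29.9% of the calls were higher against 44.6% in the main setting. With normexp background correction there were 629 and 679.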

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

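The tests in this part were chosen after the result was seen. Genes on opposite sides of HCT116 in the 2 clones were singled out as a difference between groups. With 1 array per clone, none of these differences was tested. As log2 ratios of HCT/OHP5 over HCT/OHP1, the squamous epithelial genes were LY6D (9.45), DSG3 (8.75 from its measured signals, at least 8.28 as a bound), TRIM29 (6.72), KRT14 (6.57), KRT17 (6.12) and KRT42P (5.44). Other genes on opposite sides were S100P (8.79), FUT3 (7.655), LCN2 (6.71), MRC2 (−5.59), CKM (5.72 from its measured signals, at least 5.05 as a bound) and DIRAS3 (−9.06 from its measured signals, −7.24 as a bound). DSG3 and CKM were not well above background in HCT/OHP1, nor was DIRAS3 in HCT/OHP5. Of the gene lists, p53 targets (median −0.69) and cholesterol and fatty acid synthesis (median 1.24) lay on opposite sides of HCT116 and outside the random lists in both clones, which was also not tested. The cholesterol list had 0 of 25 genes past 2-fold in HCT/OHP5 and fell to percentile 93.5 there with the mean of all probes of a gene, inside the random lists. Among probes without a gene symbol, which the comparisons did not use, 119 were at least 2-fold higher in both clones and 259 at least 2-fold lower.

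The lower signals of hypoxia, glycolysis and cholesterol genes in HCT/OHP1 were weighed against technical causes. A trend of the ratio with signal could lower such bright genes together. After loess correction the median of their 64 genes was −1.11 against −1.29 before, so removing the trend changed it little, which argues against this. It was still below all random lists, but these were matched on signal before the correction as well, so their percentile adds little. Dilution by RNA of host cells would lower epithelial genes as well. The median of these 64 genes was lower than that of the epithelial list by a log2 difference of −1.34 (95% bootstrap interval −1.66 to −0.69 over genes). These genes were taken up because their lists were low, so a lower median followed from that choice. The interval holds no spread between tumours. The difference therefore does not decide on dilution. The epithelial list itself had a median of 0.049 in HCT/OHP1, so it was not lowered in this sample. A difference in oxygen, size or sampling site between single tumours may give the same pattern and remains open, since the median of −1.11 rests on 1 tumour sample per source.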

How the results depend on the processing

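No paired analysis was possible because there was 1 array per source. For the same reason no array could be left out and samples could not be split otherwise. Counts are given as higher and lower for HCT/OHP1 and for HCT/OHP5 against HCT116, for HCT/OHP5 against HCT/OHP1, for both clones, and then as genes on opposite sides. With normexp background correction they were 782 and 647, 463 and 315, 629 and 679, 179 and 140, and 25. The added offset shrinks ratios of dim probes. With a 3-fold threshold they were 783 and 464, 476 and 344, 522 and 689, 195 and 153, and 29. Without a filter on dim probes, counts that left the range of 1.5 times the main ones were 2499 higher in HCT/OHP1, 1648 higher and 1474 lower in HCT/OHP5, 810 higher and 628 lower in both, and 178 on opposite sides. With only genes above background on every array, 223 genes were lower in both clones and the correlation was 0.464. The log2 ratio of PTPRC turned to 0.27 in HCT/OHP1 with normexp, and the median of leukocyte markers between the clones turned to −0.15 with only genes above background on both arrays. The cause was not tested for these turns. All other counts stayed within 1.5 times the main ones, including those with loess correction and E1A scaling, which were added after the data were seen. Of 358 log2 ratios of named genes, 50 moved by more than the SD between probes with the mean of all probes, 236 with normexp and 6 with quantile normalization. Of 37 list medians outside the random lists (of 75), 26 stayed outside in every setting. The authors' value table, median and E1A scaling shift all genes of an array alike and so cannot move a percentile. Keeping outlier spots moved 0 of them. Quantile normalization lost 1 and added 3, loess correction lost 3 and added 2, normexp lost 4 and added 1, and the mean of all probes lost 4 and added 1. Restriction to genes above background on every array lost 6 and added 2, and no filter on dim probes lost 5 and added 2. Signal over background limits the ratios of the 305 higher and 183 lower genes in HCT/OHP1 that are bounds.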

Other observations

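The lists and tests in this part were chosen after the result was seen. Beyond the fixed lists, HCT/OHP1 had higher signals of antigen presentation genes of MHC class II, with 7 of 10 measured genes at least 2-fold higher and 0 lower (median log2 ratio 3.56). HLA-DQB1 was 31-fold higher, the invariant chain gene CD74 29.8-fold and HLA-DRB1 17.3-fold. Other members did not match these. HLA-DRA was at least 8.67-fold higher but read 69.0 in HCT/OHP1 beside 8168.1 for HLA-DRB1, and HLA-DMA was at 1.03-fold. HLA-DQA1 and CIITA were not well above background in HCT116 or HCT/OHP1. In HCT/OHP5 2 of 11 were higher (median 0.67), with HLA-DRA at least 19.1-fold. Squamous epithelial genes were lower in HCT/OHP1 for 13 of 23 genes (median −2.04) and higher in HCT/OHP5 for 14 of 23, with 1 lower (median 1.69). TP63 and IVL of this list were not well above background on any array. KRT5 and KRT14 are also in the fixed list of skin markers, and whether tumour or host cells gave the squamous signals is not known. The desmocollin gene DSC3 was at least 24-fold lower in HCT/OHP1 and 2.35-fold higher in HCT/OHP5, and the cornified envelope gene SPRR2A at least 5.2-fold lower and 22.3-fold higher. Acute phase and secreted defence genes were higher for 8 of 15 in HCT/OHP1, with 1 lower (median 1.51), and for 12 of 17 in HCT/OHP5 (median 4.15), among them SLPI (51.3-fold in HCT/OHP5) and complement factor CFB (11.1-fold and 34.6-fold). HLA, SPRR and keratin genes are families of close paralogues whose probes may read one another (SPRR2A, 22.3-fold, is 1 of them). The squamous and acute phase lists hold genes already named for their large ratios, such as KRT14, LY6D, SAA1 and C3. S100A8 and S100A9 counted as measured only because they were above background in HCT/OHP5, and HLA-DRA was dim in HCT116. The counts and medians of these lists may therefore be raised by selection and only describe their members.

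Skeletal muscle genes were higher in HCT/OHP1, and 2 sources were weighed as hypotheses. Host muscle in the tumour sample would raise most muscle genes, and 59.5% of 37 measured genes were at least 2-fold higher, against 25.8% of 31 in HCT/OHP5. The list was written after the result and holds genes that prompted it, such as ATP2A1, TNNI2 and MYL1. Members such as MYH4 and AMPD1 counted as measured only because they were above background in HCT/OHP1. This share is therefore raised by selection and is not counted as support for host muscle. Yet of ACTA1, CKM and MB, which are abundant in muscle, 0 were 2-fold higher, and 2 were lower, CKM (at least 3.45-fold) and MB (2.54-fold). These 2 were the only lower genes of the 37, and 22 were higher. Among the higher were MYH4 (at least 74.5-fold), AMPD1 (at least 34.1-fold), PVALB (33.3-fold) and ACTN3 (13.1-fold). MYH7 (1.76-fold), TNNI1 (1.81-fold) and TNNT1 (log2 ratio −0.51) did not reach 2-fold. The 3 abundant genes therefore do not stand for the list and do not settle the question. The probes are human and how well they match mouse sequence is unknown, so host muscle stays undecided. A myogenic programme of the tumour cells would raise its transcription factors, but of 8 factors 0 were higher in HCT/OHP1, with 4 measured, which leaves this undecided as well.

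A set of 62 probes was at least 32-fold lower in HCT/OHP1, and 48 of them lay within 0.5 of a median log2 ratio of −2.60 in HCT/OHP5. If many of these probes read 1 abundant RNA by cross-hybridisation, their ratios should spread no more than those of probes of 1 gene. The robust SD of all 62 was 0.334 against 0.21 for probes of 1 gene on the same measure, which is wider but by less than 2 times, so this explanation stays undecided. Other probes of the same genes seldom went along (1 of 4 genes, against 31 of 41 genes that were 4 to 32-fold lower), and the robust SD was 1.72 for 92 probes 8 to 32-fold lower. Cells like HCT116 in the HCT/OHP5 tumour would set a floor for all such genes, but 30 probes bright in HCT116 lay more than 1 log2 unit below −2.60, such as those of ANXA10, SLC38A5 and TNFSF4, which argues against it. A shared regulation of the genes was not tested and stays open.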
